A study of Mus musculus with 40 samples.

How the data were processed

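Bulk RNA was measured in 23 tumour libraries and 9 cell line libraries, and single CD45+ cells in 8 tumour samples. The bulk tables hold raw read counts for 20695 gene identifiers as deposited, 20666 of them with a symbol; reads were aligned with STAR to mm10, and the authors compared groups with DESeq2, per the submitters' processing notes, which do not name the counting tool or the annotation. The single-cell table holds the natural log of 1 plus counts per 10000 for 12190 genes as deposited, made with Cell Ranger 3.0.2 and Seurat 2.4 per the submitters' processing notes. The exponential of each value minus 1 summed to 10000 in each cell, and each value was a whole multiple of the smallest one of its cell, so the counts behind the values could be recovered.

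Groups were taken from sample titles and library names. The deposited columns of the Brca2 KO cell lines carry another name than the titles and were assigned as a group by elimination, and the single-cell suffixes were read as 3 WT, 2 Brca1 KO and 3 Brca2 KO samples; 1 further Brca1 KO sample failed quality control per the labels. Library totals were 31.8 to 40.7 (counts in units of 1e6) in WT, 36.7 to 43.8 in Brca2 KO and 22.0 to 27.5 in Brca1 KO untreated tumours, 35.1 to 40.1 and 22.3 to 39.0 in anti-PD-1 Brca2 KO and Brca1 KO tumours, and 27.8 to 32.2 and 24.7 to 32.9 in Brca2 KO and Brca1 KO cell lines. The single-cell samples had 4656 to 8155 cells with a median of 2404 to 2768 counts per cell. The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined.

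Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, filterByExpr, TMM factors), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Brca2 KO was compared with WT and with Brca1 KO in fits of those 2 groups; Brca1 KO was compared with WT in a fit of the 3 untreated groups, the effects of anti-PD-1 and their difference came from a fit of the 4 KO tumour groups, and 17Q was compared with 17QQ in a fit of all cell lines. Fold changes are given as log2 with their standard error, and CPM in comparisons use the TMM factors. CPM of Ms4a1 and Glycam1 per library use TMM factors too, while CPM of Brca1 and Brca2 per group or library use plain totals. By the numbers in their library names, the 3 treated Brca2 KO tumours deviated from their group mean together with the untreated Brca2 KO tumours of the same numbers (correlations 0.18 to 0.438, each the highest of that untreated tumour); the labels do not say what the numbers mark, and no other 2 groups had every pair over 0.1. Lists were tested with camera (inter-gene correlation 0.01; with an estimated correlation and fry as alternatives) in limma 3.58.1, for lists with at least 3 measured members.

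Genes were named by a fixed rule: Brca1 and Brca2 always; the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM above 1 and no overlap between the libraries of the 2 groups; and 3 members per list with the smallest p. Glycam1 and Ms4a1, the genes with annotated copies, and further list members were singled out after their values were seen. In simulated counts with 200 changed genes, the edgeR test between Brca2 KO and WT tumours, run on 14485 genes, recovered 46.3%, 88.1% and 98.4% of changes of 0.5, 1 and 2 on the log2 scale.

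Single cells were clustered from 2000 variable genes, 30 principal components and 20 nearest neighbours with leidenalg 0.10.2 (resolution 1, 29 clusters; alternatives 0.5 and 2), on igraph 0.11.9 and scikit-learn 1.9.0. A cluster took the name of a cell type where at least 3 of its markers were detected in at least 5% of cells and its marker score was at least 1 and led by at least 1. It stayed unnamed where markers of another type outnumbered its own among its 10 leading genes, where called doublets were many or where counts per cell were few. Shares were tested with an exact permutation test in numpy 2.4.6. Expression was tested with limma (eBayes with a trend) on the log2 of the mean per sample and class plus 0.1 counts per 10000, in the 7 classes with at least 30 cells in each sample and for genes with a mean of at least 0.1. Doublets were scored with Scrublet in scanpy 1.11.5 and called at 0.8% per 1000 cells, a rate chosen after Scrublet's own thresholds had marked 145 of 53136 cells; it called 2910. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

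The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts and a stricter one, an absolute log2 fold change of at least 1, the replicate number as a block, other groupings of a fit, and each sample left out in turn; for single cells, other pseudocounts, filters, resolutions and the mean of the deposited log values. Added after the data were seen were the fits without anti-PD-1 Brca1 KO tumours 1 and 2, without called doublets, edgeR on the recovered counts, the blocks of library numbers and the medians within CD4 T-like clusters.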

Results

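The bulk libraries came from 4T1 mammary tumours that were WT (parental), Brca1 KO or Brca2 KO, taken on day 14. Mice were untreated (n = 5 per genotype) or given anti-PD-1 (n = 5 Brca1 KO, n = 3 Brca2 KO). The labels call the former untreated, while their library names carry IgG, so whether they received a control antibody is not known. Further libraries came from Brca1 KO (n = 6) and Brca2 KO (n = 3) cell lines. The single-cell samples held CD45+ cells sorted from untreated tumours on day 12 (n = 3 WT, n = 2 Brca1 KO, n = 3 Brca2 KO). The labels do not say whether replicates are separate animals, so the p-values measure the spread between these samples. The library names give WT and Brca2 KO tumours one submission letter and Brca1 KO tumours another, so in every contrast of tumours with Brca1 KO the genotype and the submission cannot be told apart. Library names of the bulk tumours give no line, and the single-cell suffixes give each genotype a single line name. A difference between lines therefore cannot be told apart from genotype in any contrast of tumours, Brca2 KO against WT included.

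Transcripts of the targeted genes were present in each group. Brca1 averaged 27.2 ± 11.5 CPM (mean ± SD) in WT, 30.3 ± 6.91 in Brca2 KO and 24.7 ± 8.36 in Brca1 KO untreated tumours. It was 26.6 or more in each anti-PD-1 Brca2 KO tumour, 16.2 to 25.8 in anti-PD-1 Brca1 KO tumours, and averaged 53.4 ± 9.09 and 29.2 ± 2.49 in Brca2 KO and Brca1 KO cell lines. Brca2 averaged 18.4 ± 5.79 CPM in WT, 23.9 ± 3.23 in Brca2 KO and 30.1 ± 8.19 in Brca1 KO untreated tumours. Its averages were 26.7 ± 1.91 and 23.9 ± 3.72 in anti-PD-1 Brca2 KO and Brca1 KO tumours, and 28.1 ± 8.61 and 59.0 ± 3.81 in Brca2 KO and Brca1 KO cell lines. In the cell lines Brca1 was higher in Brca2 KO (log2 fold change 0.86 ± 0.11 SE) and Brca2 was lower there (-1.08 ± 0.16). Between untreated tumours Brca2 was higher in Brca1 KO than in WT (0.65 ± 0.20). Neither gene passed the test in the other tumour contrasts. A frameshift can leave the transcript in place, so gene-level counts do not check the genotype labels.

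Untreated Brca2 KO tumours carried more transcripts of the interferon response than WT tumours. Of 23 interferon-stimulated genes, 21 rose (21 adjusted over the list alone) and 2 did not pass the test. Mx1, an antiviral GTPase, rose from 9.77 ± 1.21 to 29.0 ± 5.42 CPM (log2 fold change 1.57 ± 0.14 SE). Usp18, which restrains interferon signalling, rose by 1.48 ± 0.15, and Oasl2 by 0.92 ± 0.10. Antigen presentation by MHC class II moved with them, with 7 of 8 genes higher (8 adjusted over the list alone), among them Ciita, its master regulator (1.48 ± 0.22), and Cd74, the invariant chain (1.34 ± 0.29). In the cytosolic DNA sensing list 5 of 8 genes rose, including Zbp1 (0.91 ± 0.14) and Irf3 (0.34 ± 0.07), and none fell. Zbp1 is also a member of the interferon list, so the 2 lists overlap.

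Lymphocyte markers were also higher in Brca2 KO than in WT tumours: 8 of 13 T cell genes (11 adjusted over the list alone), such as Lat (1.25 ± 0.34) and Lck (0.96 ± 0.24). Of 12 cytotoxic genes 7 rose, such as the CD8 chain Cd8b1 (1.79 ± 0.39) and Ifng (1.36 ± 0.31). WT tumour 1 stood above the rest of its group in the cytotoxic list (mean log2 CPM 3.42 against 2.02 to 2.31 in the other 4) and in the macrophage list (7.89 against 6.81 to 7.11). Of 12 macrophage genes 6 rose, including Csf1r, the receptor for colony-stimulating factor (0.70 ± 0.09). Of 11 neutrophil genes 6 fell, including S100a8 (from 67.4 ± 16.7 to 9.53 ± 7.90 CPM) and Retnlg, and 1, Mmp9, rose. Markers of other tissue differed too. Of 9 adipocyte genes 4 rose, including Retn (2.36 ± 0.63) and Adipoq (2.09 ± 0.56), and of 14 fibroblast and matrix genes 2 fell, Pdgfra (-1.25 ± 0.22) and Dcn (-1.25 ± 0.25). The fibroblast share was near that of all genes, of which 1904 of 14582 fell. Neither any of the 9 B and plasma cell genes nor any of the 16 proliferation genes passed the test. The T cell call of camera (adjusted p = 0.00179) was not kept with an estimated correlation (adjusted p = 0.788).

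Epithelial genes rose and hypoxia genes fell in the same tumours. In the epithelial list 9 of 14 genes were higher (10 adjusted over the list alone): Cldn7, a tight-junction claudin, by 1.72 ± 0.12, Esrp1, an epithelial splicing factor, by 1.14 ± 0.11 and Grhl2 by 0.78 ± 0.07. In the hypoxia and glycolysis list 9 of 12 genes were lower, with log2 fold changes of -1.61 ± 0.26 for Ndrg1 and -0.83 ± 0.14 for the mitophagy gene Bnip3. Of 11 dissociation and handling stress genes 8 fell, Dusp1 with -1.36 ± 0.19. Fn1 (-0.96 ± 0.22) and Vim (-0.86 ± 0.13), both expressed by mesenchymal cells, fell among 12 genes of the epithelial-mesenchymal transition list, of which 3 passed the test. That share was not above the 27.7% of all genes that passed. Outside the lists, Csta1 (4.96 ± 0.37), the epithelial sodium channel subunit Scnn1b (4.88 ± 0.70) and the interleukin-17 receptor gene Il17re (3.14 ± 0.27) had large rises. Otop1 (-5.48 ± 0.42), Rasef (-4.07 ± 0.21) and Angptl7 (-4.01 ± 0.25; 67.0 to 4.16 CPM) fell far. In all, 4034 of 14582 genes differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2130 were higher and 1904 lower in Brca2 KO, and 682 had an absolute log2 fold change of at least 1. Camera called 9 of 30 lists, 6 higher and 3 lower, and none with an estimated correlation. There the interferon list had an adjusted p = 0.577, as did the epithelial, stress and neutrophil lists. The hypoxia, MHC class II and DNA sensing lists had 0.609 and the cytotoxic list 0.788.

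**Figure D1:**
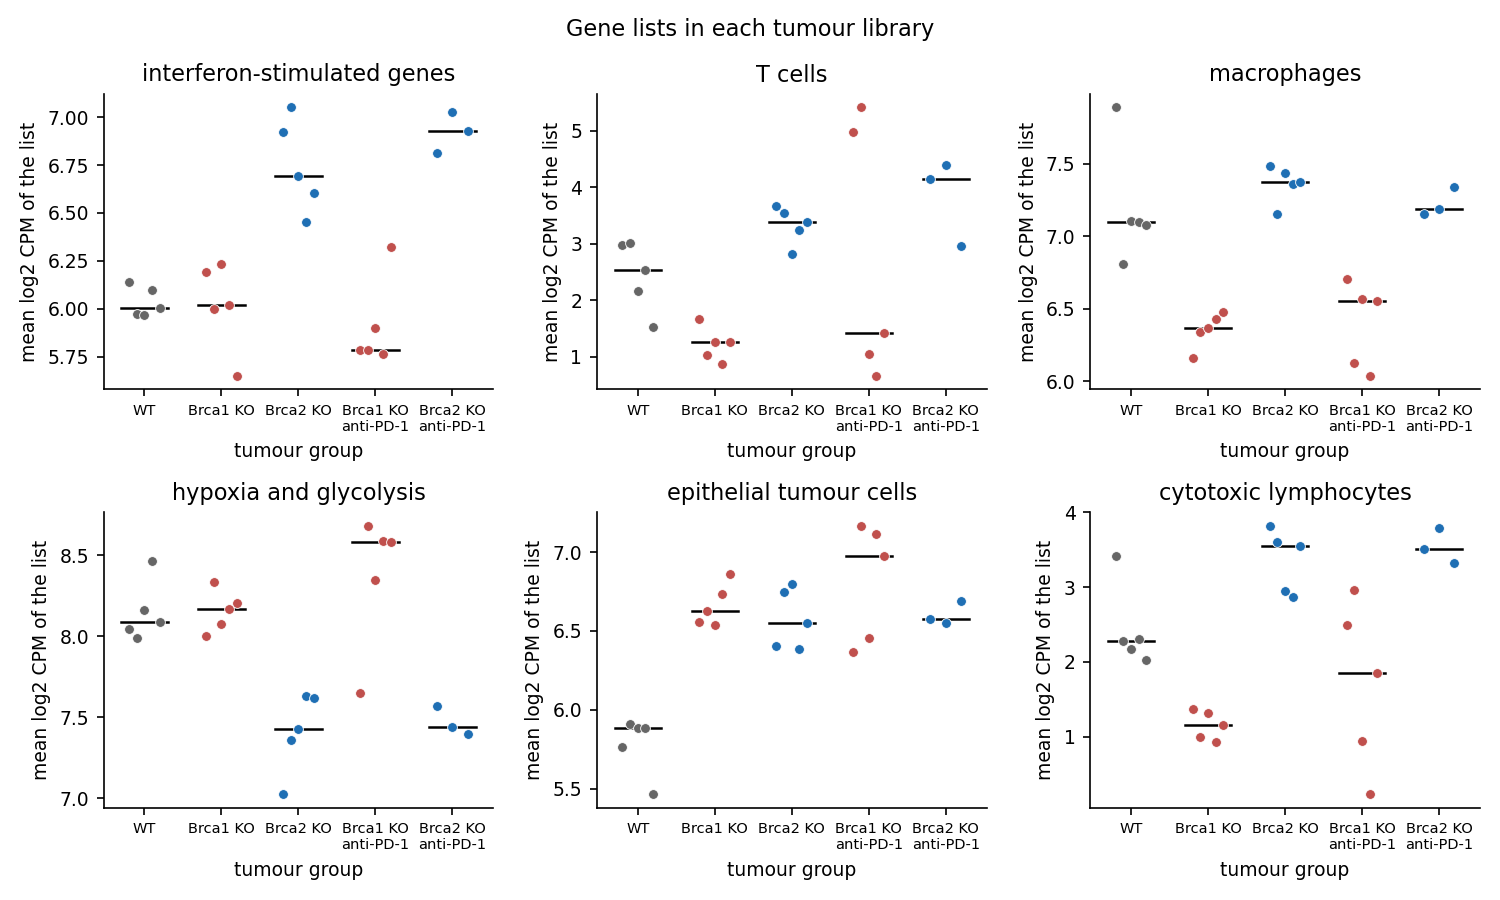
Mean log2 CPM of 6 gene lists in each tumour library (points; black line, group median) for WT, Brca1 KO and Brca2 KO tumours without treatment and the KO tumours with anti-PD-1. WT tumour 1 is the high point of the macrophage panel at 7.89, and anti-PD-1 Brca1 KO tumour 5 is the high point of its group in the interferon panel at 6.32.

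Untreated Brca2 KO tumours held more lymphocyte and macrophage transcripts than untreated Brca1 KO tumours, and the differences were large. All 12 cytotoxic genes rose, among them the granzymes Gzma (log2 fold change 3.64 ± 0.43 SE) and Gzmb (50.2 ± 15.9 against 6.18 CPM on average). Of 13 T cell genes 12 rose, including Cd3d (3.34 ± 0.30) and Lat (3.04 ± 0.19). Among 8 NK genes 7 were higher, with the receptor gene Ncr1 at 2.78 ± 0.34. Among 12 checkpoint genes 9 were higher, with Icos at 2.23 ± 0.22 and Ctla4 at 1.79 ± 0.16. All 6 measured B and plasma cell genes rose, such as Cd79b of the B cell receptor (4.42 ± 0.80) and the plasma cell gene Mzb1 (5.24 ± 1.15). Cxcl13, a chemokine for B cells, rose as well (5.85 ± 1.46). Glycam1, a mucin of lymph node venules, was above 1 CPM in 4 of the 5 Brca2 KO libraries (2.18 to 12.0 CPM) and at 0.188 CPM or less in the Brca1 KO libraries. The same 4 libraries held the B cell gene Ms4a1 at 2.10 to 12.6 CPM.

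Macrophage genes rose in 11 of 12 cases in this contrast. The complement genes C1qa (812 ± 97.9 against 337 ± 50.4 CPM) and C1qb (537 ± 58.4 against 240 ± 32.5) were among them. Of 23 interferon-stimulated genes 18 were higher (19 adjusted over the list alone), led by Ifi27l2a (1.83 ± 0.17) and Bst2 (1.24 ± 0.14). So were 6 of 8 MHC class II genes and 9 of 14 MHC class I genes, including H2-K1 (0.83 ± 0.13) and B2m (0.58 ± 0.11). Endothelial genes went the other way: 8 of 10 were lower in Brca2 KO (10 adjusted over the list alone), for example Cdh5 (-1.09 ± 0.15). So were 7 of 14 fibroblast and matrix genes, such as Col6a3 (-0.98 ± 0.17) and Postn (-0.75 ± 0.14). Of 12 hypoxia and glycolysis genes 7 were lower, such as the angiogenic factor Vegfa (-1.27 ± 0.17). Brca1 KO tumour 1 stood above its group in the muscle list (mean log2 CPM 5.30 against 0.83 to 2.09). Of the 6 muscle genes 5 were lower in Brca2 KO. Proliferation genes were lower in 4 of 16 cases, Ccnb1 with -0.82 ± 0.21, a share near that of all genes (3335 of 14486).

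Cldn7 (38.5 ± 2.65 against 1.83 ± 0.455 CPM), the plasma cell gene Jchain (7.10 ± 1.53) and Scnn1b (5.49 ± 0.75) were far higher in Brca2 KO tumours. Rps23rg1 (-6.72 ± 0.27), Rasef (-5.83 ± 0.19), the glycolytic enzyme gene Eno1 (-3.02 ± 0.10) and the neurotrophin receptor gene Ngfr (-2.81 ± 0.29) were far lower. Altogether 6453 of 14486 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3118 higher and 3335 lower in Brca2 KO, with 1127 at an absolute log2 fold change of at least 1. Camera called 19 of 30 lists, 13 higher and 6 lower; with an estimated correlation none was called and the smallest was an adjusted p = 0.212 for the cytotoxic, macrophage and checkpoint lists. Genes with annotated pseudogene copies, such as Pgk1, Rpl5, Ptma and H3f3a, reached that size in 32 of 347 cases here (9.22%, against 7.75% of other genes). Between Brca2 KO and WT, which share a submission, 2 of 349 did (0.573%, against 4.78%). Only pseudogenes named after a gene, and the genes they are named after, were counted. Eno1, with Eno1b beside it, and Rps23rg1 were thus counted among the other genes. The counts do not clear these genes of reads shared with copies, here or in the other contrasts with Brca1 KO.

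Against WT, untreated Brca1 KO tumours held fewer immune transcripts of several kinds. T cell genes fell in 12 of 13 cases, including the costimulatory receptor Cd28 (log2 fold change -2.57 ± 0.43 SE) and Lck (-1.45 ± 0.27). Of 12 cytotoxic genes 7 fell (9 adjusted over the list alone), among them perforin, Prf1 (from 38.7 to 3.76 ± 0.923 CPM), and Gzmb (-2.54 ± 0.41). WT tumour 1 lay above its group in this list; without it 7 genes fell, Prf1 by 3.09 and Gzmb by 2.21 on the log2 scale. Macrophage genes fell in 11 of 12 cases, Mrc1 with -1.43 ± 0.24 and Trem2 with -1.15 ± 0.17, and in 9 of 12 without WT tumour 1, which lay above its group here too. Other markers that fell were those of NK cells (6 of 8 genes; Ncr1 -2.78 ± 0.32), neutrophils (8 of 11; S100a8 -2.37 ± 0.44) and mast cells and basophils (6 of 8; Tpsb2 -3.23 ± 0.43). So did those of dendritic cells (7 of 11; Siglech -2.85 ± 0.52) and B and plasma cells (9 of 9; Jchain -6.09 ± 1.71). The granzymes Gzmf (153 ± 69.5 to 4.39 ± 3.02 CPM) and Gzmg (-4.90 ± 0.87) fell far.

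Interferon-stimulated genes showed no common direction between Brca1 KO and WT tumours: 2 of 23 rose, Mx1 (0.88 ± 0.15) and Usp18 (0.82 ± 0.16). Another 2 fell, among them Bst2 (-0.76 ± 0.15), and 19 did not pass the test. Epithelial genes rose in 10 of 14 cases, with Esrp1 at 1.55 ± 0.10 and Grhl2 at 1.15 ± 0.06, while Cldn7 fell by 2.69 ± 0.18. In the homologous recombination list 8 of 21 genes were higher and none lower; Bard1, the partner of Brca1 protein, rose by 0.94 ± 0.23 and Palb2, which links both Brca proteins, by 0.73 ± 0.18. Brca1 KO tumour 1 stood above its group in this list (mean log2 CPM 4.73 against 4.08 to 4.23). Without it 5 of 21 genes were higher, Bard1 by 0.80 ± 0.23 and Palb2 by 0.58 ± 0.16. That share was near that of all genes, of which 3735 of 14820 were higher with all libraries in the fit. Of 14 fibroblast and matrix genes 10 rose, including Pdgfrb (0.94 ± 0.15), and 2 fell, Pdgfra (-1.76 ± 0.20) and Dcn (-1.60 ± 0.25). Large rises were seen in Rps23rg1 (6.81 ± 0.26), Ngfr (5.30 ± 0.35) and Lemd1 (5.18 ± 0.30), and Angptl7 fell by 5.86 ± 0.32. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7316 of 14820 genes differed, 3735 higher and 3581 lower in Brca1 KO, 1509 of them with an absolute log2 fold change of at least 1. Camera called 12 of 30 lists, 3 higher and 9 lower, and none with an estimated correlation (smallest adjusted p = 0.639, shared by the T cell, macrophage and epithelial lists).

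Among tumours given anti-PD-1, Brca2 KO again exceeded Brca1 KO in interferon and macrophage transcripts. Of 23 interferon-stimulated genes 18 were higher (20 adjusted over the list alone), such as Ifi44 (log2 fold change 1.78 ± 0.21 SE) and Ifit2 (1.11 ± 0.14). Of 12 macrophage genes 10 were higher, such as Adgre1 (1.25 ± 0.22) and Ms4a7 (1.06 ± 0.12). MHC class II genes rose in 6 of 8 cases, Cd74 with 1.39 ± 0.28. Cytotoxic genes rose in 4 of 12, with Gzmb at 2.69 ± 0.61 and Gzmk at 3.37 ± 0.60. The checkpoint gene Pdcd1, whose product is the target of the antibody, was at 11.6 ± 2.51 CPM in Brca2 KO and 2.72 in Brca1 KO. None of the 13 T cell genes or the 9 B and plasma cell genes passed the test (median log2 fold changes -0.10 and -1.53). Anti-PD-1 Brca1 KO tumours 1 and 2 stood above the other 3 of their group in Ms4a1 (70.1 and 114 CPM against 0.0525 to 0.270). The T and B cell results rest on them: without both, left out after their values were seen, 12 of 13 T cell genes were higher in Brca2 KO (median 3.57), as were 10 of 12 cytotoxic genes and 6 of 7 B and plasma cell genes (median 5.04). That fit left out libraries of the Brca1 KO group only. Brca2 KO tumours 1 and 2, which were kept, held Ms4a1 at 10.1 and 17.4 CPM and Glycam1 at 6.55 and 38.4 CPM. In Brca2 KO tumour 3 these were 0.215 and 0.0269 CPM, so the B cell median is not a trait of the whole group.

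Hypoxia and glycolysis genes were lower in the treated Brca2 KO tumours in 7 of 12 cases, among them Adm, a hypoxia-induced peptide gene (-2.12 ± 0.45), Eno1 (-2.69 ± 0.15) and Pgk1 (-1.13 ± 0.20). Of the 7, Pgk1 has annotated pseudogenes named after it. Other names, such as Eno1b beside Eno1, were not counted as copies, so Eno1 is not cleared by this. Of 10 endothelial genes 4 were lower, among them Cdh5 (-1.07 ± 0.14). Dissociation and handling stress genes such as Fos (-1.54 ± 0.28) were lower too. Without anti-PD-1 Brca1 KO tumours 1 and 2, 9 of 11 stress genes were lower and none higher. Stfa3 (4.22 ± 0.40) and Cldn7 (37.3 ± 4.62 against 2.06 ± 0.446 CPM) were far higher. Rps23rg1 (-7.39 ± 0.94), Rasef (-6.04 ± 0.33) and the muscle actin Acta1 (-6.27 ± 1.91) were far lower. In this contrast 2043 of 14959 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1188 higher and 855 lower, 521 of them at an absolute log2 fold change of at least 1. Camera called 16 of 30 lists, 8 in each direction, and with an estimated correlation none (adjusted p = 0.514 for the interferon, macrophage and endothelial lists). The count of genes was 3274 in a fit of all 4 KO tumour groups and 2970 without anti-PD-1 Brca1 KO tumours 1 and 2. It was 1274 and 1257 without Brca1 KO tumour 4 or 5, and 897, 668 and 334 without Brca2 KO tumour 1, 2 or 3.

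Anti-PD-1 gave no gene that passed the test within either genotype. In Brca2 KO tumours (n = 3 treated, n = 5 untreated) T cell genes had a median log2 fold change of 0.71 and interferon-stimulated genes of 0.09. The genes with the smallest p were Zfp389 (1.30 ± 0.27 SE), Vamp8 (-0.29 ± 0.07) and Ttc14 (0.29 ± 0.07). In Brca1 KO tumours (n = 5 each) they were Tex15 (3.04 ± 0.58), Adk (-0.34 ± 0.06), Glycam1 (11.14 ± 2.38) and Fcer2a, an IgE receptor gene of B cells (9.77 ± 2.19). The B and plasma cell list had a median of 6.98 with 0 of 9 genes called over all genes and 9 adjusted over the list alone. These B cell values came from anti-PD-1 Brca1 KO tumours 1 and 2; without both libraries the median was 0.50. The T cell list, with 12 of 13 genes called over the list alone (median 3.45), and the dendritic cell list, with 7 of 12 (median 1.76), were also among the 7 of 30 lists called by camera in Brca1 KO tumours. Without tumours 1 and 2 their medians were -0.28 and 0.19, with 0 genes called over the list alone. With an estimated correlation the T cell list had an adjusted p = 0.728, and the dendritic cell and B and plasma cell lists each had an adjusted p = 0.675.

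Adipocyte genes were the 1 list that camera called in Brca2 KO tumours (0 of 9 genes called, adjusted p = 0.956 with an estimated correlation). Of 15254 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 in Brca2 KO (smallest adjusted p = 0.701; 1045 at an unadjusted p under 0.05; DESeq2 22, limma-voom 0), 0 in Brca1 KO (0.190; 2726; DESeq2 480, limma-voom 0) and 0 for the difference between the genotypes (0.419; 1681; DESeq2 5). With untreated and treated Brca2 KO tumours paired by the number in their library names, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14937 genes (smallest adjusted p = 0.453; 1590 at an unadjusted p under 0.05). In that fit camera called 5 of 30 lists, and 0 with an estimated correlation. For the difference between the genotypes Selenow (-0.43 ± 0.10) and Tubgcp4 (0.50 ± 0.11) were among the smallest p. In simulated counts with these group sizes the test recovered 71.2% of genes changed by 1 on the log2 scale in Brca2 KO. It recovered 73.1% in Brca1 KO and 52.2% for the difference. Effects of this size, and smaller ones, could thus be missed.

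**Figure D2:**
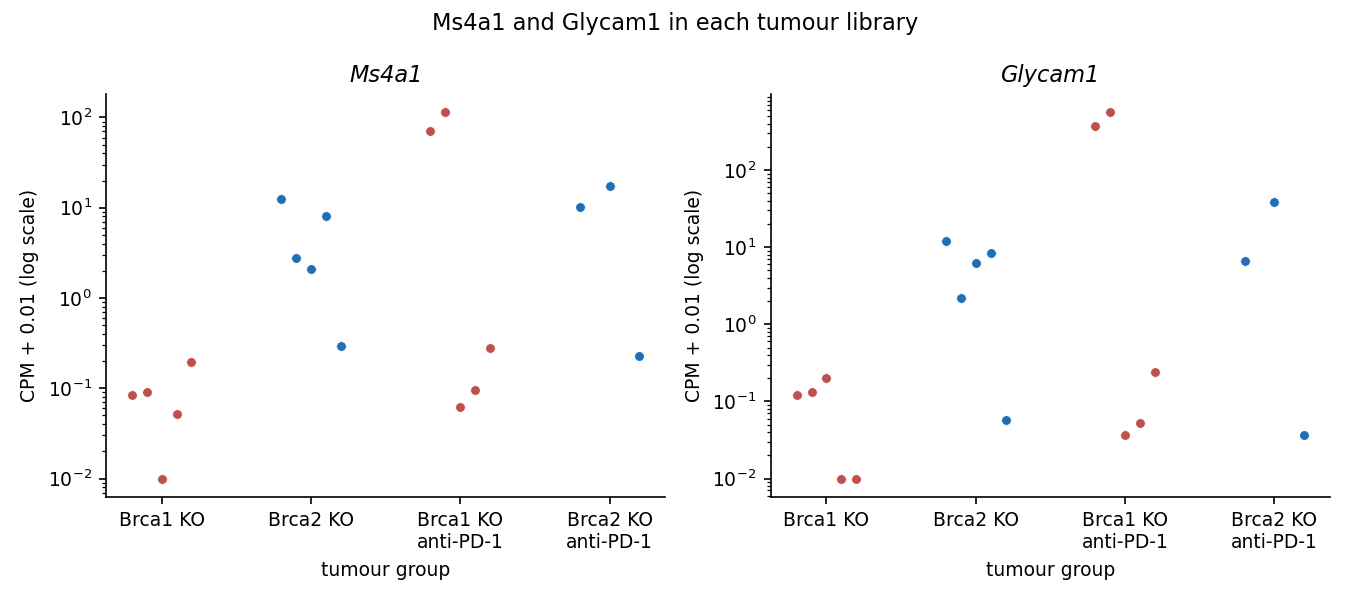
CPM plus 0.01, on a log scale, of the B cell gene Ms4a1 and of Glycam1 in each KO tumour library (points), by genotype and treatment. Anti-PD-1 Brca1 KO tumours 1 and 2 lie at 70.1 and 114 CPM for Ms4a1 and at 377 and 563 CPM for Glycam1, above every other library plotted.

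In culture, without tumour tissue around them, Brca2 KO cells had fewer interferon and DNA repair transcripts than Brca1 KO cells. The Brca2 KO libraries carry 1 line name and the Brca1 KO libraries 2, so genotype and line cannot be told apart. Of 21 interferon-stimulated genes 10 fell and none rose, among them Ifit2 (log2 fold change -1.24 ± 0.10 SE) and Oasl1 (-1.13 ± 0.11). This was the reverse of the direction in tumours, where 18 of 23 were higher in Brca2 KO. Against 17Q alone 15 of 21 genes were lower in Brca2 KO cells and none higher (median -0.70), and against 17QQ alone 7 of 20 were lower and 2 higher (median -0.36). Of 21 homologous recombination genes 11 fell (12 adjusted over the list alone), such as Fancd2 (-0.76 ± 0.09), Atm (-0.77 ± 0.12) and Bard1 (-0.66 ± 0.07), and 2 rose. The proliferation genes with the smallest p, Cenpf, Mki67 and Ccna2, were lower as well, though camera did not call the proliferation list. Whether the repair and proliferation differences are linked was not tested. The mesenchymal gene Vim (0.82 ± 0.07) and the transcription factor Twist1 (0.72 ± 0.11) rose. Sfrp1, a secreted Wnt inhibitor, rose from 1.34 ± 1.44 to 22.4 ± 0.345 CPM. Hexa, a lysosomal enzyme gene (8.62 ± 2.39 to 0.0704 ± 0.0391 CPM), Bcl3 (-5.45 ± 0.32) and Tmcc2 (-5.66 ± 0.30) fell far. A total of 5493 of 11846 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2684 higher and 2809 lower in Brca2 KO, 608 with an absolute log2 fold change of at least 1. Camera called the interferon and homologous recombination lists of 18; each had an adjusted p = 0.519 with an estimated correlation.

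The Brca1 KO libraries came as 3 named 17Q and 3 named 17QQ, which differed in 4082 of 11846 genes (2128 higher and 1954 lower in 17Q; 715 at an absolute log2 fold change of at least 1). Cldn7 was at 82.2 CPM in 17Q and 2.20 ± 0.300 in 17QQ, Rasef at 0.0485 and 26.1 ± 1.60, and B4galt6, a sphingolipid enzyme gene, at 0.0135 and 34.3. Kazn averaged 8.79 CPM in 17Q and was listed at 0 in the 17QQ libraries. Interferon-stimulated genes were higher in 17Q in 11 of 21 cases (12 adjusted over the list alone), such as Ddx58 (log2 fold change 0.89 ± 0.12 SE). This was the 1 list of 18 that camera called (adjusted p = 0.485 with an estimated correlation). Cd74 was higher too (2.17 ± 0.13). Brca1 and Brca2 did not pass the test between them (-0.20 ± 0.10 and -0.12 ± 0.15).

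Cell lines and untreated tumours shared part of the Brca2 KO against Brca1 KO difference. Of 11705 genes tested in both, 1000 were higher in Brca2 KO in both, where 533 would fall together if the calls were independent (odds ratio 3.45, two-sided Fisher's exact test p = 8.95e-132), and 1195 were lower in both, against 681 (3.27; p = 2.69e-137). Another 263 and 207 were called in opposite directions. Spearman's rho across genes was 0.345, and genes are not independent replicates. With only the 17Q libraries as Brca1 KO, rho was 0.262. The shared counts were then 1065 and 1246, against 686 and 834 for independent calls, with 499 and 390 in opposite directions. With only the 17QQ libraries rho was 0.411 and the shared counts 1129 and 1317, against 556 and 712, with 246 and 174 in opposite directions. At an absolute log2 fold change of at least 1 in both, 41 genes were higher and 45 lower.

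Single CD45+ cells from the tumours were mostly T cells, B cells and neutrophils. Of 53136 cells in 8 samples, the CD4 T-like class made up 37.1 ± 6.41% (mean ± SD of samples) in Brca2 KO, 38.7 ± 1.82% in Brca1 KO and 34.2 ± 7.91% in WT. In the same order, the B-like class held 18.5 ± 2.72%, 15.1 ± 1.25% and 19.2 ± 5.27%, and the CD8 T-like class 17.3 ± 3.38%, 18.5 ± 3.45% and 17.7 ± 1.84%. Neutrophil-like cells were 5.32 ± 4.04%, 8.17 ± 0.811% and 6.78 ± 2.61%, and regulatory T-like cells 4.41 ± 0.492%, 3.90 ± 0.443% and 4.12 ± 0.409%. Macrophage-monocyte-like cells were 2.11 ± 1.43%, 1.57 ± 0.786% and 1.92 ± 1.45% and NK-like cells 1.83 ± 0.864%, 1.01 ± 0.124% and 0.862 ± 0.379%. Cells in clusters without a named class were 9.88 ± 1.04%, 11.2 ± 1.27% and 12.0 ± 3.15%. None of the 13 classes differed in share by an exact permutation test of the F statistic over 560 arrangements of the samples (smallest adjusted p = 0.911; smallest unadjusted p = 0.150, for NK-like cells). Between Brca2 KO and WT, with n = 3 each, a two-sided exact permutation test cannot give a p below 0.1. B-like cells were 15.1% of sorted Brca1 KO cells on day 12, yet untreated Brca1 KO bulk tumours of day 14 held Ms4a1 at 0.1845 CPM or less. Shares of sorted cells may thus differ from those in the tumour, and the cause was not tested.

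Within these classes, neutrophil-like cells of Brca2 KO tumours differed most from those of WT tumours, and interferon-stimulated genes led. Of 21 such genes 19 rose (21 adjusted over the list alone), with a list median of 1.67 on the log2 scale. Rsad2, an antiviral enzyme, rose from 5.23 ± 2.70 to 30.9 ± 3.67 counts per 10000 and Ifit1 from 2.07 ± 1.18 to 10.2 ± 1.43. Ifit3b, which is not in the list, rose from 0.375 ± 0.159 to 3.09 ± 0.295. MHC class I genes rose in 6 of 14 cases (13 adjusted over the list alone), with an adjusted p = 0.157 with an estimated correlation. Prok2 (-1.79 ± 0.41 SE), the carbonic anhydrase gene Car4 (-1.46 ± 0.33) and Stfa2 (-1.40 ± 0.19) fell. Against Brca1 KO, 16 of 21 interferon-stimulated genes rose in the same class (20 adjusted over the list alone), Ifit2 by 2.32 ± 0.43. Outside the list, Slfn5 rose by 2.10 ± 0.26 and Prok2 fell by 1.91 ± 0.45. With an estimated correlation the interferon list had an adjusted p = 0.0684 against WT and an adjusted p = 0.127 against Brca1 KO.

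Macrophage-monocyte-like cells had no interferon-stimulated gene that passed over all genes, while 19 of 23 did over the list alone against WT (median 0.91), with an adjusted p = 0.228 with an estimated correlation. In CD4 T-like cells the same list was higher in Brca1 KO than in WT. There 0 of 19 genes passed over all genes, 17 adjusted over the list alone, with a median of 0.74 and an adjusted p = 0.0576 with an estimated correlation. This class joins 2 clusters, and the one led by interferon-induced genes such as Iigp1 and Ifit1 held 16.9 ± 3.21% of cells in Brca1 KO and 9.26 ± 1.86% in WT. The list median was 0.61 within that cluster and 0.23 within the other. B-like cells had the same direction, with 16 of 21 genes adjusted over the list alone, a median of 1.01 and an adjusted p = 0.464 with an estimated correlation. By limma with Benjamini-Hochberg adjustment, the neutrophil-like class had 119 of 5153 genes called between Brca2 KO and WT (96 higher, 23 lower), 112 between Brca2 KO and Brca1 KO (55 and 57) and 0 between Brca1 KO and WT (173 at an unadjusted p under 0.05). Outside that class 4 calls were made, Ifitm1 in NK-like cells (3.09 ± 0.42, Brca2 KO against Brca1 KO), and 3 more. These were the tetraspanin gene Cd9 (-1.39 ± 0.20, Brca2 KO against WT) and Lrg1 (-2.40 ± 0.25, Brca2 KO against Brca1 KO) in macrophage-monocyte-like cells, and Trbv15 in regulatory T-like cells (2.35 ± 0.33, Brca1 KO against WT). In B-, CD4 T- and CD8 T-like cells limma called 0 genes in each contrast, with 227 to 628 at an unadjusted p under 0.05. The CD8 T-like class does not hold cluster 18, an unnamed cluster with CD8 T as its best type and interferon-induced genes such as Ifit3 leading. Leaving out WT sample c gave 62 calls over the 7 classes between Brca2 KO and WT. Leaving out Brca1 KO sample a or b, Brca2 KO sample a or WT sample a gave 50, 14, 175 and 53 between Brca2 KO and Brca1 KO. Without sample a or b, Brca1 KO is 1 sample, assumed to vary like those of the other groups.

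**Figure D3:**
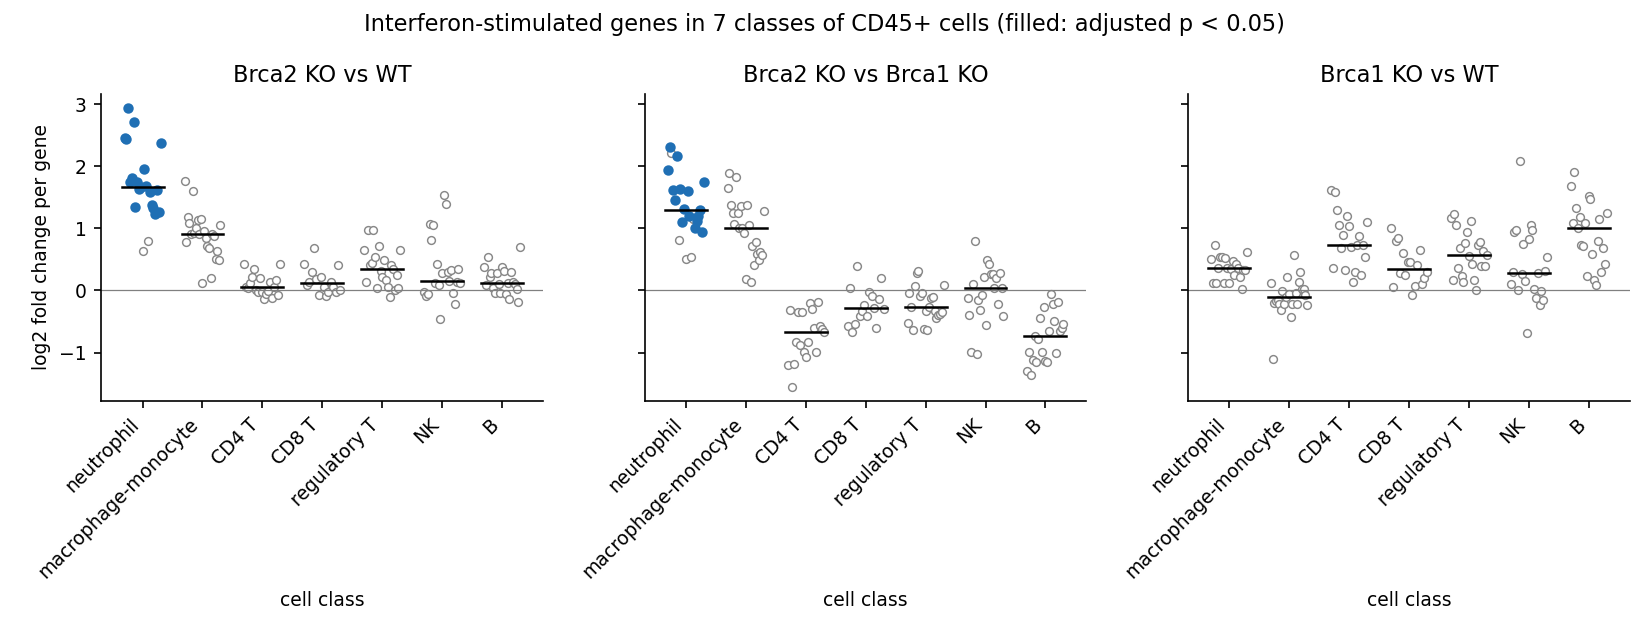
Log2 fold change of each measured interferon-stimulated gene (points; filled where the adjusted p is under 0.05; black line, median of the list) in 7 classes of CD45+ cells for the 3 genotype contrasts. The neutrophil-like class has the highest median between Brca2 KO and WT, 1.67, followed by the macrophage-monocyte-like class with 0.91.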

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

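The tests of lymph node genes, library depth, free RNA and other splits of the samples were chosen after the result was seen, as was the comparison of gene copies within 1 submission.

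In 16 cases a library lay far from the others of its group in the mean log2 CPM of a list, among 163 groups of values where chance would give 8.2. In WT tumour 1 the cytotoxic list was at 3.42 (others 2.02 to 2.31), the checkpoint list at 4.19 (3.27 to 3.49) and the macrophage list at 7.89 (6.81 to 7.11); in WT tumour 5 the dendritic cell list was at 2.13 (2.39 to 2.49). In Brca1 KO tumour 1 the muscle list was at 5.30 (0.83 to 2.09) and the homologous recombination list at 4.73 (4.08 to 4.23). In Brca2 KO tumours 2, 3 and 4 the keratinocyte, muscle and monocyte lists were at 1.15 (0.05 to 0.23), 0.85 (0.61 to 0.64) and 5.88 (6.08 to 6.13). In anti-PD-1 Brca1 KO tumour 5 the interferon list was at 6.32 (5.76 to 5.90), and in tumour 2 the p53 target list at 5.42 (5.04 to 5.11) and the keratinocyte list at 5.46 (0.03 to 0.27). In Brca1 KO cell line library 6 the neutrophil, muscle, keratinocyte and erythroid lists were at 0.52 (0.32 to 0.39), 0.65 (-0.26 to -0.05), 0.93 (0.03 to 0.25) and -0.11 (-0.43 to -0.37).

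The effect of anti-PD-1 differed between Brca2 KO and Brca1 KO tumours in 9 lists by camera, though no single gene passed. The adjusted p was 1.29e-04 for adipocytes (median -2.25), 0.0166 for stress (-0.44), interferon (0.26) and mammary epithelium (-1.55), 0.0253 for dendritic cells (-1.64), 0.0397 for B and plasma cells (-5.95) and chemokines (-0.55), 0.0411 for homologous recombination (0.16) and 0.0454 for T cells (-2.78). Without anti-PD-1 Brca1 KO tumours 1 and 2 the medians were 0.07 for dendritic cells, 0.51 for B and plasma cells and 0.89 for T cells, so these 3 rest on those 2 libraries. The others were -0.17 for chemokines and 0.10 for homologous recombination, both nearer 0 by over 1.5 times, and -1.56, -0.43, 0.19 and -1.28 for adipocytes, stress, interferon and mammary epithelium. With an estimated correlation each had an adjusted p = 0.857, and 58 of 100 splits gave 9 lists or more (up to 16), so chance cannot be excluded.

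B cell genes were far higher in anti-PD-1 Brca1 KO tumours 1 and 2 than in the other 3 of their group. Without both the list median was 0.496. This cannot decide on an effect of the antibody common to the group. The pattern itself sets these 2 libraries apart from the other 3, and the standard errors were large. Low depth is argued against by the 6 other Brca1 KO tumours no deeper than tumour 1. Their median log2 CPM of the list was at most -0.055, against 6.14 or more in both, though only 1 of the 6 is shallower than tumour 2. Of 5 lymph node genes other than Glycam1 and those of B cells, 4 lay at least 4-fold above the untreated median, or above 3 counts where that is higher, in both libraries. Ccl19 did not (0.0681 and 0.0423 CPM), and lymphoid tissue formed in the tumour would carry the same genes, so lymph node tissue in the sample cannot be told apart from it; a response to the antibody in those 2 tumours stays open and was not tested.

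Genes with named copies, Pgk1 and Rpl5 among them, were far apart between Brca1 KO tumours and those of the other submission. A genotype difference of the tumour cells is argued against, since 10 of 26 had the same sign in the cell lines (38.5%, CI 20.2 to 59.4). Between Brca1 KO and WT, calls of at least 1 were no more frequent among genes with copies (odds ratio 0.760, CI 0.495 to 1.13), which by the bound of 1.2 set beforehand would argue against reads shared between copies. That bound took 1 as the value without such an effect, while the ratio within 1 submission was 0.115 (CI 0.0139 to 0.420), so the bound was wrong. Between Brca2 KO and Brca1 KO the ratio was 1.21 (CI 0.809 to 1.75) in untreated and 2.17 (CI 1.37 to 3.30) in treated tumours, so the contrasts disagree and shared reads cannot be told apart from other differences between the submissions.

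Interferon-stimulated genes were higher in neutrophil-like cells of Brca2 KO than of WT tumours, with a list median of 1.67. Free RNA of the sample is argued against by a median of at most 0.117 in CD4 T- and B-like cells, a different mix of the 2 neutrophil-like clusters by 1.57 and 1.80 within them, and doublets by 1.62 without those called. The other classes had medians of 0.113 (CD8 T-like), 0.15 (NK-like), 0.342 (regulatory T-like) and 0.908 (macrophage-monocyte-like). The argument against free RNA thus rests on the classes with low medians. A response of neutrophil-like cells to interferon in Brca2 KO tumours may be the cause, as a hypothesis from the same data. With 3 samples each there are 10 splits, too few for a share under 0.05 (119 genes, highest other split 44).

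Chance can be excluded as the source of the gene counts in 4 contrasts of tumours. These were Brca2 KO and WT (4034, highest other split 108), Brca2 KO and Brca1 KO (6453, 523), Brca1 KO and WT (7316, 2125) and the treated tumours (2043, 406). There 1 split, the real one, of 100, 100, 100 and 56 gave as many. In the cell lines (5493, 2590) 1 split of 84, the real one, gave as many. The 9 cell line libraries are 3 lines with 3 libraries each, so they are not independent. Their splits therefore cannot exclude chance, nor a difference between lines in place of one between genotypes. For tumours the splits do not exclude a difference between lines either. Brca2 KO cell line library c lay apart: the chi-square per degree of freedom between counts was 53.9 and 46.5 with libraries a and b. It was 7.89 between a and b. Chance cannot be excluded for the counts of lists called by camera: 54 of 100 splits gave as many as the 9 between Brca2 KO and WT (up to 19), 14 of 100 the 19 between Brca2 KO and Brca1 KO (21), 23 of 100 the 12 between Brca1 KO and WT (17), 12 of 56 the 16 in treated tumours (20), 55 of 56 the 1 and 79 of 100 the 7 for anti-PD-1 in Brca2 KO and Brca1 KO (18 and 16) and 14 of 84 the 2 in cell lines (3). For anti-PD-1, 0 genes were found in Brca2 KO, in Brca1 KO and for their difference, a count that all 56, 100 and 100 splits reach by construction, so these comparisons test nothing; other splits gave up to 3, 70 and 1 genes, and the 70 point to a structure of the samples. The 10 splits of 17Q and 17QQ were too few (4082 genes, highest other 0; 1 list, given by 6 splits, highest other 3). The same holds for B- (0 genes, highest other 262), CD4 T- (0; 392), CD8 T- (0; 302), NK- (0; 42), regulatory T- (0; 133) and macrophage-monocyte-like cells (1 gene, given by 2 splits; 32), where such splits point to a structure of the samples.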

How the results depend on the processing

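The fits without doubted libraries, without called doublets, with edgeR on recovered counts and with a block of library numbers were chosen after the data were seen. Under the alternatives set at the start, 7809 values kept direction and side of the threshold, 727 no longer passed it, 11 newly passed it, 8 moved and 5 reversed; of the added ones 162 kept it, 32 no longer passed, 1 moved and 1 reversed. The cause was not tested where no cause is named.

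At an absolute log2 fold change of at least 1, which calls fewer genes by construction, the counts were 682, 1127, 1509 and 521 for Brca2 KO against WT, Brca2 KO against Brca1 KO, Brca1 KO against WT and the treated tumours, 608 and 715 for the cell lines and 17Q, and 41 and 45 for the genes shared by cell lines and tumours. In treated tumours a replicate block gave 67 genes, a fit of 4 groups 3274 and leaving out each library 334 to 1956. DESeq2 called 22 genes for anti-PD-1 in Brca2 KO, 480 in Brca1 KO and 5 for the difference, and the replicate block 19 in Brca1 KO; the cause was not tested. The replicate numbers of the titles did not pair the tumours: 13 of 39 same-number pairs correlated over 0.1 (-0.323 to 0.484) and 11 were best with their own number. Here and in the tally by library names, pairs of untreated Brca1 KO and Brca2 KO tumours are counted both among the untreated groups and among the KO groups. The anti-PD-1 Brca2 KO tumours 1, 2 and 3 are numbered 2, 4 and 5 in the library names; by those, 13 of 39 pairs correlated over 0.1 (-0.389 to 0.441), 13 were best with their own number, and the replicate block gave 968 genes in treated tumours, 4 for anti-PD-1 in Brca1 KO and 0 in Brca2 KO and for the difference. Only untreated and treated Brca2 KO tumours met the bound for pairs by library number; a block in a fit of these 2 groups gave 0 genes and turned Brca1 to 0.036, not past the threshold, and the cause was not tested. For cell lines and single cells, no paired analysis was possible because numbers in column names could not be tied to titles or (17Q, 17QQ) titles share none.

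With an estimated correlation 0 lists were called in each comparison; fry called 8 in treated tumours, 0 for both anti-PD-1 effects and their difference, 13 in cell lines and 7 for 17Q. In single cells, Brca2 KO against WT gave 52 genes without a filter, 199 from log values and 62 to 176 leaving out each sample; Brca2 KO against Brca1 KO gave 10, 336 and 14 to 175, and 50 with edgeR; Brca1 KO against WT gave 0 with a pseudocount of 0.02, 4 with 0.5, 0 without a filter or with a mean of at least 0.5, 6 from log values, 2 with edgeR and 0 to 12. Brca1 turned to -0.032, -0.051 and -0.075 between Brca2 KO and WT without Brca2 KO tumour 2, WT tumour 1 or WT tumour 5, and to 0.047 and 0.026 for anti-PD-1 in Brca2 KO without untreated or treated tumour 2, never past the threshold (ranges over left-out libraries -0.075 to 0.263 and -0.19 to 0.047); the cause was not tested. Leaving out each library gave 3038 to 4213, 5330 to 6608 and 6652 to 7467 genes in the untreated tumours and 4105 to 5471 and 2951 to 3451 in the cell lines.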

Other observations

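The test of the 17QQ line below was chosen after the result was seen.

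Cluster 2 of the single cells, of the CD4 T-like class, held 16.9 ± 3.21% of cells in Brca1 KO (mean ± SD), 8.68 ± 0.583% in Brca2 KO and 9.26 ± 1.86% in WT samples, and cluster 18, without a name, 2.37%, 0.775% and 0.539%. Cluster 18 had CD8 T as its best type (marker score 1.97), with Ifit3, Ifit1 and Mx1 among its leading genes. The monocyte marker Ly6c2 among its leading genes kept it unnamed. Brca1 KO samples had at least 14.6% in cluster 2 and 2.20% in cluster 18. Every other sample had at most 11.1% and 1.01%. Neither difference was tested.

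Brca1 KO tumours may share expression with the 17QQ rather than the 17Q line: Cldn7 was low and Rasef high in both. Across 11705 genes the difference of 17QQ from 17Q correlated with that of Brca1 KO from Brca2 KO tumours with a Spearman rho of 0.122, and 1189 of 1906 genes called in both had the same sign (62.4%); genes are not independent replicates. The single-cell Brca1 KO samples carry the 17QQ name.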
